A study of Homo sapiens with 8 samples.

How the data were processed

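The series holds 8 libraries made by eCLIP, in which RNA is crosslinked to protein by ultraviolet light, immunoprecipitated and sequenced. All came from HEK293T cells, an immortalised human embryonic kidney line that carries the SV40 large T antigen. For TIA1 and for RBFOX2 there were 2 immunoprecipitated libraries (clip) and 2 input libraries, made from RNA that was not immunoprecipitated. Per the labels' protocols, cells were crosslinked with 600 mJ of ultraviolet light. The labels name an anti-HA tag antibody for every clip library. One protocol text also names beads bound to TIA1 for all 8 libraries, and the labels call the replicates biological in one place and technical in another, so the kind of replicate is not settled. The design text also names APOBEC and SLBP, which were not analysed here.

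The authors deposited 1 peak list per protein. The sample descriptions tie each list to all 4 libraries of its protein, and its title sets replicate 1 against replicate 2, so each list is a joint product of both replicates. The submitters' processing notes list UMI-tools 1.0.0, cutadapt 1.14, STAR 2.4.0i and SAMtools 1.6, and the hg19 build, without saying what each did. The peak caller is not given in the sources used here. Each deposited row gives a chromosome, a start, an end, a −log10 p, a log2 fold and a strand. The lists have no header. The deposited column taken as −log10 of a p-value never falls below 3.01 and stops at 400, and the deposited column taken as a log2 fold never falls below 3.00. Both units were inferred from these ranges, and the fold was read as clip over input because those are the libraries the authors list for each file. Every fold and p per peak is thus the authors' own value. The lists hold no value per replicate and no read counts, so the depth is unknown and no spread between replicates can be given. Peaks left out by the authors' thresholds are not seen, and a fold near 3 on the log2 scale is truncated by that limit.

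Coordinates are given 1-based in hg19. The annotation at hand was for GRCh38, with no genome sequence. As a check of the build, deposited peaks were set against GRCh38 genes without any conversion. Only 42.4% of TIA1 peaks and 41.9% of RBFOX2 peaks fell in a gene on the same strand, against 29.6% and 30.8% on the opposite strand, so that annotation was not used. Location in exons, introns and untranslated regions, gene names, the planned gene lists, the share of peaks with GCATG and the share with TTTTT need hg19 and were not analysed here. Sites are therefore named by position.

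Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and bedtools 2.31.1. Peaks of the lists were called overlapping when they shared at least 1 base on the same strand. The chance level came from moving every peak of one list by 1 to 10 kb in a random direction, 1000 times, with a one-sided permutation p. Shares of peaks have 95% Clopper-Pearson intervals. Because peaks of one transcript lie close together and are not independent, intervals were also drawn by a bootstrap over 1 Mb windows with 1000 draws, and these are the intervals printed unless the other is named. Chromosome shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 25 chromosomes, first on peaks and then on windows with at least 1 peak. Closeness was the share of peaks with another peak of the list within 1 kb on the strand, with the RBFOX2 list drawn down to the length of the TIA1 list 100 times. All intervals describe the peaks of these lists and not the spread between libraries.

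The peaks named are, per protein, the 10 with the highest −log10 p, ties ordered by log2 fold, the 5 with the highest log2 fold and the 5 windows of 1 Mb with most peaks, a rule fixed before the data were examined. Alternatives were a log2 fold of at least 4, a −log10 p of at least 5, merging of peaks within 50 bases, equal list length, other overlap rules, shorter moves, a 10 kb distance and leaving out chromosomes M, X and Y. A merged site took the highest log2 fold and −log10 p of its peaks. Leaving out the densest window of each list, leaving out peaks under 20 bases and moves of 100 to 150 bases were added later. The procedures were tested on simulated data built from the real positions. With 30% of TIA1 peaks planted in a list moved far away, 30.02% were found. The planted peaks were exact copies, so this checks only the counting of overlaps. Of 50 intervals for a planted log2 fold difference of 0.2, 94% held it. These simulated folds were drawn independently for each peak, so the result does not test the intervals where neighbouring peaks are alike. Random deals of single peaks into lists break up clusters and do not test the chromosome comparison, so the list names of the real peaks were instead swapped window by window in 100 draws, an addition made after the data were seen.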

Results

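RNA bound by TIA1 and by RBFOX2 was mapped by eCLIP in HEK293T cells, with 2 clip and 2 input libraries per protein. TIA1 is an RNA-binding protein that prefers U-rich RNA and takes part in splicing and in stress granules. RBFOX2 is a splicing regulator that binds the element GCAUG. The series title places these libraries in a study of the RNA targets of such proteins. The lists allow the sites of each protein to be described and the sites of both proteins to be compared. Each list joins both replicates, so no replicate check was possible and every test compares 2 lists of peaks.

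The TIA1 list held 3215 peaks that covered 210.1 kb, and the RBFOX2 list held 4227 peaks that covered 310.6 kb. TIA1 peaks had a median width of 61 bases (interquartile range 27 to 94), and RBFOX2 peaks of 70 bases (37 to 101). Many peaks abutted one another: 662 TIA1 and 1133 RBFOX2 peaks began at the base after the end of a neighbour. With peaks within 50 bases joined, 2413 TIA1 and 2749 RBFOX2 sites remained. The densest joined site held 16 TIA1 peaks, and for RBFOX2 it held 23. The −log10 p had a median of 7.36 in TIA1 (95% interval 7.03 to 7.78) and 6.77 in RBFOX2 (6.49 to 7.13). It stood at its upper limit of 400 in 65 TIA1 peaks and 29 RBFOX2 peaks.

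The peaks that ranked highest in each list were described first, once by −log10 p and once by fold. Rank by −log10 p is not a measure of binding strength, since it also depends on read depth and is limited at 400, where fold decided the order. The 10 TIA1 peaks that ranked highest by −log10 p, all at 400, fell at 3 sites on plus strands. On chromosome 2, 6 of them ran from position 232573240 to 232573341, with log2 folds from 4.82 to 5.48. On chromosome 9, a peak at 131451605 to 131451610 had a log2 fold of 4.58, and one at 131451630 to 131451651 had 4.84. On chromosome 1, a peak at 109643078 to 109643093 had a log2 fold of 4.69, and one at 109643101 to 109643108 had 4.54. The chromosome 2 and 9 peaks overlapped RBFOX2 peaks, and those on chromosome 1 did not.

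The TIA1 peaks with the highest folds lay elsewhere, apart from the chromosome 2 peak at 232573329 to 232573341. On chromosome 12, abutting peaks on the plus strand at 124082155 to 124082164 and 124082165 to 124082197 had log2 folds of 6.37 and 5.94, which correspond to 82.5-fold and 61.4-fold. A 14-base peak on the minus strand of chromosome 21, at 34143817 to 34143830, had a log2 fold of 6.13 and overlapped an RBFOX2 peak. The next was on the minus strand of chromosome 20, at 524335 to 524435, with a log2 fold of 5.51. The −log10 p of these 4 peaks lay between 13.8 and 41.2.

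The 10 RBFOX2 peaks that ranked highest by −log10 p were also all at 400. On the plus strand of chromosome 1, abutting peaks at 116947132 to 116947218 and 116947219 to 116947282 had log2 folds of 4.99 and 5.02. On the plus strand of chromosome 19, peaks at 47112785 to 47112827 and 47113549 to 47113569 had log2 folds of 4.47 and 4.68. On the plus strand of chromosome 9, 5 peaks between 131451512 and 131451627 had log2 folds from 4.0 to 4.08. The last was on the minus strand of chromosome 1, at 59249180 to 59249277, with a log2 fold of 4.0. Of these 10 peaks, only the 5 on chromosome 9 overlapped TIA1 peaks. With peaks within 50 bases joined, the sites on chromosome 19 (47113499 to 47113643) and on the minus strand of chromosome 1 (59249035 to 59249306) also overlapped TIA1 peaks.

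By fold, the first RBFOX2 peak was a 7-base peak on the plus strand of chromosome 19, at 47112843 to 47112849, with a log2 fold of 6.19 (73.0-fold). Peaks on the plus strand of chromosome 12, at 74934878 to 74934964 and 74934982 to 74935040, had log2 folds of 5.97 and 6.07. A minus-strand peak on chromosome 10, at 119042189 to 119042265, had 5.90. A plus-strand peak on chromosome X, at 114884176 to 114884192, had 5.87 and was the only one of these 5 to overlap a TIA1 peak.

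Peaks were spread over 1017 windows of 1 Mb in the TIA1 list and 1098 in the RBFOX2 list. The 5 densest windows held 168 TIA1 peaks, 5.23% of the list, and 141 RBFOX2 peaks, 3.34%. The TIA1 window with most peaks was chromosome 21 from 47 to 48 Mb, with 48 peaks, 47 of them on the plus strand, against 13 RBFOX2 peaks. Next were chromosome 8 from 145 to 146 Mb, with 34 TIA1 and 7 RBFOX2 peaks, and chromosome 1 from 19 to 20 Mb, with 33 and 20. Chromosome 16 from 2 to 3 Mb held 28 TIA1 peaks and led the RBFOX2 list with 35. Chromosome 16 from 88 to 89 Mb held 25 TIA1 and 5 RBFOX2 peaks, tied with 1 other window. The other dense RBFOX2 windows held few TIA1 peaks. Chromosomes 19 (47 to 48 Mb) and 4 (77 to 78 Mb) had 27 RBFOX2 peaks each, against 4 and 1 TIA1 peaks. Chromosomes 12 (110 to 111 Mb) and 1 (59 to 60 Mb) had 26 each, against 7 and 2. On chromosome 1 all 26 lay on the minus strand between 59247515 and 59249571, with a median log2 fold of 4.22.

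Fold per peak was then set side by side between the proteins. RBFOX2 peaks had the higher folds, with a median log2 fold of 3.48 (95% interval 3.46 to 3.51) against 3.36 (3.34 to 3.37) for TIA1. The difference of 0.13 (95% interval 0.099 to 0.16) amounts to a 1.09-fold ratio and exceeded the bootstrap spread over windows. A log2 fold of at least 4 was reached by 815 RBFOX2 peaks, 19.3% of the list (95% interval 17.4 to 21.1%). Among TIA1 peaks 296 reached it, or 9.21% (7.92 to 10.5%). Above that level the medians differed by 0.024, with an interval of -0.031 to 0.090. The 2 lists come from separate immunoprecipitations whose yield and depth are not known, so the difference is one of the deposited values.

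**Figure D1:**
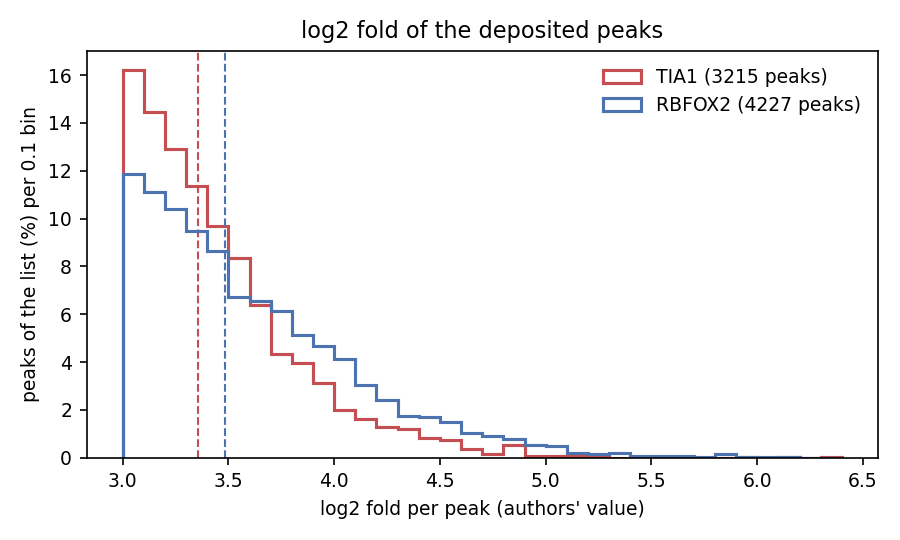
Share of the peaks of each list (vertical axis, percent per bin) by log2 fold per peak (horizontal axis, the authors' value). Dashed lines mark the medians, 3.36 for TIA1 and 3.48 for RBFOX2, and the RBFOX2 list has the larger share of peaks with a log2 fold of at least 4 (19.3% against 9.21%).

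The central comparison was whether the proteins occupied the same sites. Of the 3215 TIA1 peaks, 773 overlapped an RBFOX2 peak on the same strand, or 24.0% (95% interval 21.8 to 26.6%, Clopper-Pearson 22.6 to 25.6%). Of the 4227 RBFOX2 peaks, 916 overlapped a TIA1 peak, or 21.7% (19.8 to 23.5%, Clopper-Pearson 20.4 to 22.9%). On the opposite strand 1 peak of each list overlapped, 0.031% of TIA1 and 0.024% of RBFOX2 peaks. The overlaps were spread over 428 windows of 1 Mb. Moving TIA1 peaks by 1 to 10 kb left a mean of 4.49 overlaps and at most 14 in 1000 draws. Moving RBFOX2 peaks left a mean of 4.88 and at most 13. The one-sided permutation p was 0.001 in both directions, the smallest that 1000 draws can give. With overlap of at least 50% of each peak required, the shares were 16.3% of TIA1 and 12.4% of RBFOX2 peaks. Moves of this length can leave the exon or the transcript, so the chance level is not one for positions within the same RNA. With moves of 100 to 150 bases, added after the data were seen, a mean of 12.3% of TIA1 peaks still overlapped, and at most 13.5%. Joined sites had median widths of 78 bases in TIA1 and 102 in RBFOX2. Peaks moved so little can still meet the same site, so this level is not one of chance alone.

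**Figure D2:**
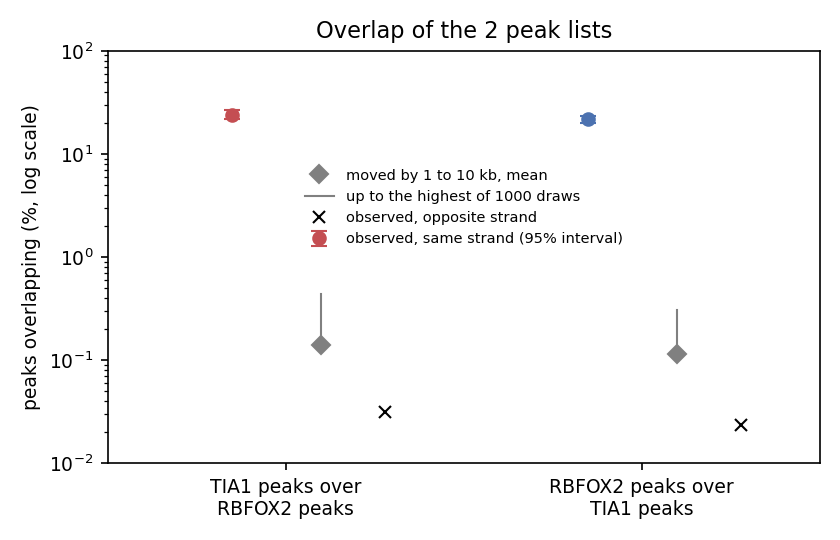
Percent of the peaks of one list that overlap the other (vertical axis, log scale), with the 95% interval from windows of 1 Mb. The observed 24.0% of TIA1 and 21.7% of RBFOX2 peaks lie above the grey mean of the moved peaks, whose line ends at the highest of 1000 draws, and above the opposite-strand overlap (crosses).

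At 3 joined sites both lists reached a −log10 p of 400, a set picked out after the values were seen. On chromosome 2 the TIA1 site (232573240 to 232573341) and the RBFOX2 site (232573240 to 232573342) shared their first base. The 6 TIA1 peaks there had log2 folds from 4.82 to 5.48, and the 5 RBFOX2 peaks from 3.82 to 3.97. On chromosome 9 the TIA1 site ran from 131451527 to 131451841, with log2 folds from 3.16 to 4.84. The RBFOX2 site ran from 131451512 to 131451678, with log2 folds from 3.33 to 4.08. On chromosome 6, plus strand, the TIA1 site ran from 26156595 to 26156705 with a highest log2 fold of 4.05. The RBFOX2 site ran from 26156589 to 26156713 with a highest log2 fold of 3.27.

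**Figure D3:**
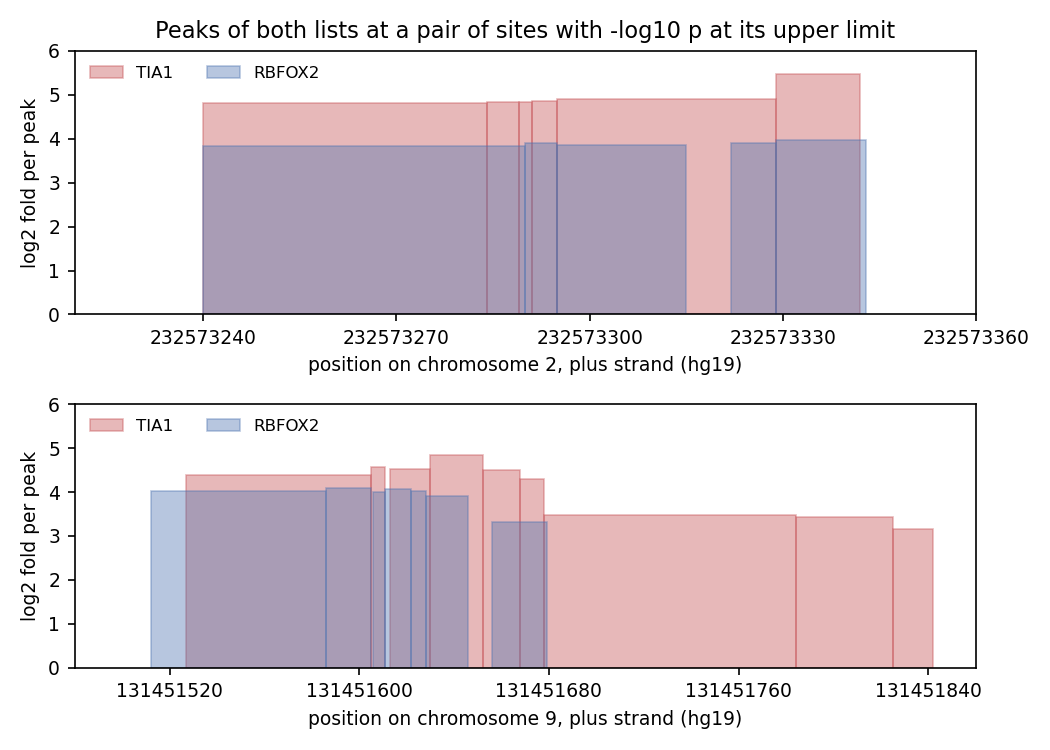
Deposited peaks of TIA1 and RBFOX2 at the chromosome 2 and chromosome 9 sites, drawn to scale as boxes from the first to the last base (horizontal axis, hg19, plus strand) with the log2 fold as height (vertical axis). At the chromosome 2 site every TIA1 peak (4.82 to 5.48) stands above every RBFOX2 peak (3.82 to 3.97).

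The share of peaks per chromosome was compared next. TIA1 peaks were more often on chromosome 19, with 8.65% of the list (95% Clopper-Pearson interval 7.70 to 9.67%) against 4.80% of RBFOX2 peaks (4.18 to 5.49%). The odds ratio was 1.88 (Fisher's exact test, adjusted p = 9.56e-10), with a window bootstrap interval of 1.31 to 2.71. No swap of the list names window by window, in 100 draws, gave an odds ratio as far from 1 on this chromosome (0 of 100). Chromosome 19 was singled out for this as the one with the lowest p of 25. Neither the swaps nor the bootstrap interval are adjusted for that choice. By peaks, 6 of 25 chromosomes passed an adjusted p of 0.05, but this test treats neighbouring peaks as independent. The swaps, which keep neighbours together, gave a mean of 3.14 calls, and 16 of 100 gave at least 6. By the same exact test, TIA1 shares were also higher on chromosome 21 (2.74% against 1.42%, adjusted p = 0.000902) and chromosome 16 (6.31% against 4.83%, adjusted p = 0.0227). RBFOX2 shares were higher, again by Fisher's exact test, on chromosome 15 (3.97% against 2.58%, adjusted p = 0.00773), chromosome X (4.31% against 2.99%, adjusted p = 0.0152) and chromosome 2 (6.70% against 5.04%, adjusted p = 0.0152). Of these 6, only chromosome 19 had a window bootstrap interval that excluded an odds ratio of 1. Counted as windows with at least 1 peak, 1017 for TIA1 and 1098 for RBFOX2, no chromosome passed (0 of 25 by Fisher's exact test, and 0 at an unadjusted p of 0.05). Of the 1353 windows with a peak, 762 held peaks of both lists, and Fisher's exact test takes the lists' windows as independent, so this count has little power to show a difference. Without the densest window of each list, chromosome 21 was not called. With peaks within 50 bases joined, chromosome 19 was the only call. Among peaks with a log2 fold of at least 4 the chromosome 19 call ended, with 22 TIA1 and 39 RBFOX2 peaks there, an odds ratio of 1.6 and an adjusted p of 0.302 (Fisher's exact test).

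**Figure D4:**
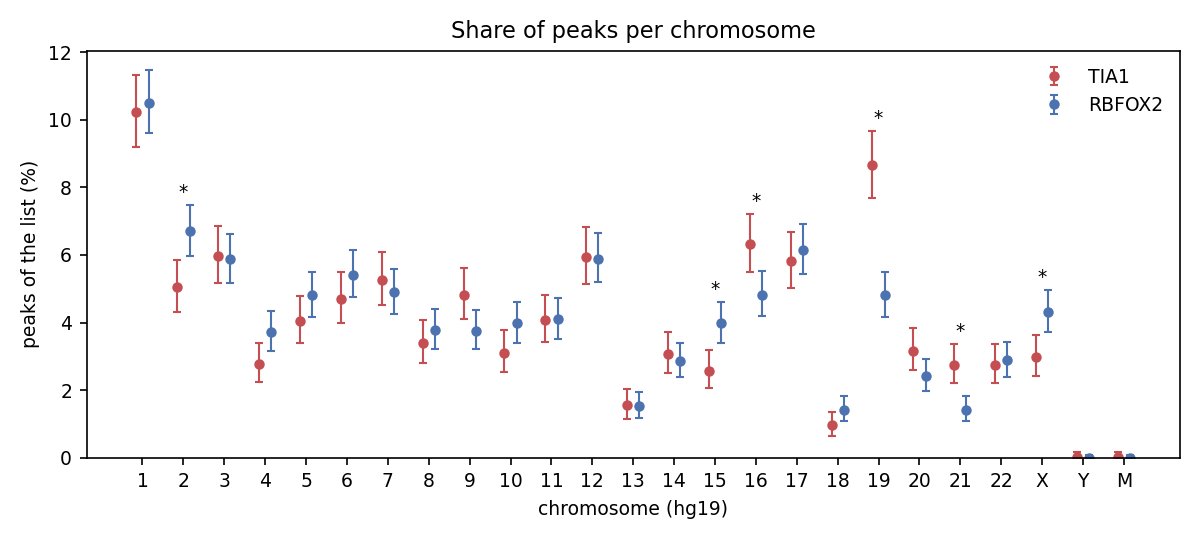
Share of each list's peaks per chromosome (vertical axis, percent), with 95% Clopper-Pearson intervals and stars at chromosomes with an adjusted p under 0.05 by peaks. Chromosome 19 holds 8.65% of TIA1 and 4.80% of RBFOX2 peaks.

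RBFOX2 peaks lay closer together than TIA1 peaks. Another peak of the list lay within 1 kb on the strand for 2809 RBFOX2 peaks, 66.5% (95% Clopper-Pearson interval 65.0 to 67.9%), and for 1725 TIA1 peaks, 53.7% (51.9 to 55.4%). At equal list length the RBFOX2 share was 61.0%. The remaining difference of 7.35 percentage points (95% interval 3.53 to 11.1) exceeded the bootstrap spread over windows. It was 6.87 points (2.98 to 10.7) when peaks within 50 bases were joined, which removes abutting peaks. With RBFOX2 cut to its 3215 peaks of highest −log10 p, the difference was 14.5 points (11 to 17.8), but this selects on −log10 p in RBFOX2 alone. With a −log10 p of at least 5 required in both lists, the difference was 5.93 points (1.57 to 9.93). Above a log2 fold of 4 it was 3.05 points, with an interval of -10.5 to 15.5, so no difference could be shown there.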

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

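The pattern in this part was seen before it was tested, and the merged, binned and chromosome tests were written down before their results were known. Overlapping peaks differed from the other peaks of their list in opposite directions in the 2 proteins. In TIA1 the 773 overlapping peaks had a median log2 fold of 3.47 against 3.33 for the other 2442 peaks, a difference of 0.14 (95% window bootstrap interval 0.080 to 0.18). In RBFOX2 the 916 overlapping peaks had 3.42 against 3.51 for the other 3311, a difference of -0.083 (-0.14 to -0.034). The contrast between the proteins was 0.22 on the log2 scale (0.15 to 0.29), and that difference is what drew attention to it.

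If splitting of broad sites into abutting peaks made the contrast, merging peaks within 50 bases was predicted to make it vanish. After merging the contrast was 0.23 (0.15 to 0.30). The TIA1 part alone was then 0.19 (0.13 to 0.22). The RBFOX2 part alone was -0.043, with an interval of -0.10 to 0.013 that includes 0. This test cannot decide, because a joined site took the highest log2 fold of its peaks, which can only rise as peaks are joined. Splitting therefore remains open. If the higher −log10 p of overlapping peaks made it, it should vanish among peaks of like −log10 p, but the mean within 4 equal bins was 0.26 (0.20 to 0.31). Without the 6 chromosomes called by peaks the contrast was 0.24 (0.17 to 0.31). A difference in binding between the proteins, and a difference in depth or yield between the immunoprecipitations, both remain open, since the lists hold no read counts. Overlapping peaks also differed in width from the others, with medians of 79 against 54 bases in TIA1 and 65 against 71 in RBFOX2. Whether width made the contrast was not tested, so it remains open too.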

How the results depend on the processing

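The overlap of the lists stayed above its chance level under all 11 alternatives per direction, from 9.12 to 28.1% of TIA1 peaks and from 4.79 to 26.7% of RBFOX2 peaks. Both lowest shares came from requiring a log2 fold of at least 4. The limit applied to both lists and left fewer peaks to overlap, so the lower shares do not show that peaks of high fold overlap less. That limit left 296 TIA1 and 815 RBFOX2 peaks, reduced the difference in median log2 fold from 0.13 to 0.024 and the difference in closeness from 7.35 to 3.05 percentage points, with intervals that include 0. It also left 2 chromosomes called by peaks, 20 and 21, and ended the call of chromosome 19. The fewer peaks widen the closeness interval by construction, and beyond this the cause was not tested. Merging peaks within 50 bases left 2749 RBFOX2 peaks and 1 chromosome called by peaks (chromosome 19). Otherwise 5 to 7 chromosomes were called by peaks, and none by windows under any of the 6 alternatives (0 in each). The fold difference stayed between 0.12 and 0.18 and the closeness difference between 5.04 and 14.5 points under the remaining alternatives, with intervals that exclude 0. No paired analysis was possible because each list joins both replicates and holds no value per replicate. For the same reason no replicate could be left out. The alternatives for location classes, GCATG, T runs and gene lists were not run for want of an hg19 reference. Leaving out the densest windows, leaving out peaks under 20 bases and moves of 100 to 150 bases were chosen after seeing the data. The depth of the libraries is not known, so peaks missing from one list cannot be read as absence of binding.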

Other observations

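The comparisons in this part were chosen after the overlap of the lists was seen, as were the test on unsplit peaks and the tests with moves of up to 500 bases. The other tests of the explanations for it were written down before their results were known. The sites of highest −log10 p were shared in part. Joined within 50 bases, 20 TIA1 sites and 8 RBFOX2 sites reached a −log10 p of 400, and 7 of the 20 and 5 of the 8 overlapped any peak of the other list. TIA1 sites without an RBFOX2 peak included the plus strand of chromosome 1 from 109642956 to 109643152, with 16 peaks and a highest log2 fold of 4.69. Another was the plus strand of chromosome 20 from 57466450 to 57466631, with 10 peaks and a highest log2 fold of 4.51. On chromosome 11 a pair of TIA1 sites at 809970 to 810041 and 810234 to 810289 had highest log2 folds of 3.66 and 3.55, and neither overlapped an RBFOX2 peak. RBFOX2 sites without a TIA1 peak were on chromosome 1 (116947064 to 116947282), chromosome 19 (47112555 to 47112939) and chromosome 6 (26156964 to 26157043). The chromosome 6 site lies close to the one that both proteins share, at 26156589 to 26156713. The TIA1 list also held a peak placed on chromosome M at 9723 to 9796, with a log2 fold of 3.06 and a −log10 p of 34.3. A peak placed on chromosome Y at 10037820 to 10037878 had a log2 fold of 4.52 but a −log10 p of only 5.19. Each was the only peak of either list on its chromosome. Whether their reads were placed correctly could not be checked, so neither is established as a TIA1 site.

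Peaks with higher −log10 p overlapped the other list more often. In TIA1 the share rose from 14.8% (95% interval 12.0 to 17.9%) in the lowest of 4 equal bins of −log10 p to 35.8% (30.4 to 41.5%) in the highest. In RBFOX2 it rose from 7.0% (5.45 to 8.74%) to 40.7% (36.2 to 45.6%). Among 773 overlapping pairs the TIA1 peak had the higher log2 fold in 56.1% (52.2 to 59.8%), with a median difference of 0.064 (0.031 to 0.11). This is the opposite of the whole lists, where RBFOX2 had the higher median. Of the TIA1 peaks without an overlap, 131 lay within 50 bases of an RBFOX2 peak and 134 at 50 to 250 bases. A further 45 lay at 250 to 500 bases and 48 at 500 to 1000 bases. These ranges differ in width, so their counts cannot be compared as densities.

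Splitting of broad sites does not account for all of the overlap, since 234 of 1879 unsplit TIA1 peaks (12.5%) overlapped unsplit RBFOX2 peaks (1974 in all), 29.2 times the highest draw. Against all RBFOX2 peaks, 21.2% of unsplit and 32.8% of split TIA1 sites overlapped, while the 44.2-fold excess of merged sites decides nothing, because merging cannot remove an overlap. Unrelated positions spread evenly along unspliced stretches of over 1 kb are argued against as the whole cause. Moves of 250 to 500 bases should leave at least 50% of the overlaps there but left 14.1% on average. The observed count was 5.52 times the highest draw (2.76 times for 150 to 250 bases, 26.7 times for 0.5 to 2 kb). No peak was assigned to such a stretch, and uneven placement along one was not tested. Within shorter exons unrelated positions stay open, because moved peaks leave the exon and overlaps fall with distance even there. The 26.7 therefore does not decide there, nor do the 1.78 for moves of 100 to 150 bases and the 1.21 for 50 to 100 bases. A background common to both anti-HA immunoprecipitations may also raise the same positions, and the log2 folds of overlapping pairs correlated weakly across peaks, which are not independent replicates (Spearman's rho 0.16, 95% interval 0.071 to 0.24, which spans the bound of 0.1 set for this test), so background and binding of both proteins cannot be told apart, for want of a control immunoprecipitation in the lists analysed.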
